A study of Mus musculus with 2 samples.

How the data were processed

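MicroRNA (miRNA) levels were measured in knee joint cartilage of male mice aged 8 weeks with 2 one-colour Agilent mouse miRNA arrays, 1 of a control sample and 1 of a sample labelled Col2a1Tsc1KO. Per the labels' protocols, articular cartilage was peeled from the knee and washed, and total RNA was extracted and labelled with a commercial miRNA labelling kit. How many mice each sample held is not given in the sources used here. Both arrays lay on 1 slide, so the group and the position on the slide cannot be told apart, and no other batch could be examined.

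Per the file headers and the submitters' processing notes, the deposited scanner files came from Agilent Feature Extraction 10.7, which located the spots, subtracted background with spatial detrending and wrote a background-subtracted intensity, a raw mean intensity and a local background intensity for each spot, with no scaling between arrays. Each array held 52044 spots, of which 49880 were spots of 3101 probes for 1247 mouse miRNAs, and each probe well above background on both arrays had between 7 and 38 usable spots on each array. The submitters also deposited a table of log2 values, 1 row per miRNA or control. How it was made is not given in the sources used here, so its scale, centring and direction were checked against the scanner files. Quantile normalization of the log2 total signals, after a running sum held by the software's totals was removed and with undetected miRNAs set to 0.1 and tied values averaged, gave differences between the columns that deviated from the deposited log2 values by a median of 5.83e-05 over 304 miRNAs. Column medians of that table were -3.26 for control and -3.32 for the knockout, which are also its floors. It is on a log2 scale, is forced to 1 distribution with no further centring, and has the direction of the signals.

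For the main setting, spots marked as outliers were dropped and the log2 background-subtracted intensity was averaged over the spots of a probe. A probe counted as well above background on an array when over 50% of its spots were marked so. Each array was scaled to its 75th percentile over the 476 probes well above background on both arrays, and the difference of a miRNA, knockout minus control, was the mean over such probes. Errors are standard errors over spots within the arrays and hold technical noise alone. The number of arrays limits the precision. With 1 array per group no p-value was computed, and an absolute log2 difference of 1, which is 2-fold, served only as a threshold for counts. A miRNA well above background on 1 array alone received a bound, the bright signal over the higher of the lowest signal well above background on the dim array and the dim probe's own signal, both after scaling.

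The analysis plan, the alternatives and 27 lists of miRNAs were fixed before the data were examined. The lists were chondrocyte, osteoarthritis, mTOR targeting, Runx2 targeting, let-7, miR-17~92, miR-15/16, miR-29, miR-30, miR-232724, miR-181, miR-34, miR-199 and miR-214, inflammation, hypoxia, Dlk1-Dio3, H19 and Igf2, muscle, erythroid, leukocyte, endothelial, fibroblast and smooth muscle, osteoblast, adipocyte, epithelial, neural and liver. Of their 253 entries, 248 had probes in the files used, and the other 5 were not analysed here. For a list with at least 3 members well above background on both arrays, the median difference was set against 10000 random lists of the same size, drawn for each member from the miRNA itself and its 20 neighbours in level. Its percentile describes these arrays and is no test of the genotype. The named miRNAs were the 12 highest and 12 lowest whose probes all differed in 1 direction by over 2 standard errors and were not saturated, the 5 largest bounds in each direction, the 2 highest and 2 lowest members of each list, and, whatever their values, miR-140-5p, miR-140-3p, miR-455-3p, miR-483-5p and the members of the chondrocyte, muscle, erythroid, leukocyte and endothelial lists. A miRNA named outside this rule is marked as chosen after its values were seen.

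The steps were tested on simulated data made from the control array and a copy of it with changes in 30 miRNAs upward and 30 downward of 257. All 60 simulated changes were recovered and no unchanged miRNA passed the threshold. After centring on the unchanged miRNAs, 94.9% of the true differences lay within 2 standard errors. The changes put in exceeded the threshold and were balanced, and both sides had the control array's spot noise. Recovery was thus likely from the start, and the simulation does not measure the error from the choice of scaling. In the same simulation 5 of 60 unshifted lists fell in the lowest or highest 2.5%.

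Alternatives covered the scaling (75th percentile over all probes, median, quantile, none), background correction with normexp (offset 50) followed by quantile normalization, the software's total gene signal, the brightest probe only, other filters on dim probes, the deposited log2 values, outlier spots kept and other thresholds. A floor setting kept dim probes instead of leaving them out. A miRNA at the floor on both arrays then had the same difference, -0.56, set by the floors and the scaling. A sign that turns, or a low list median, with a floor can thus come from dim probes and members alone. Scaling to the 4 added spike-ins, the total gene signal with a running sum removed, and random lists matched for the range of miRNA numbers (below 200, 200 to 399, 400 to 699, 700 and above) as well as for level, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and R 4.3.3 with limma 3.58.1 were used. Probe positions are those given in the files. The file headers name the mouse build mm9, but the files list positions of more than 1 build, and 3029 of the 3101 probes, or 97.7%, had a listed position inside a miRNA gene of the GRCm38 gene table. The positions printed are of that kind, on GRCm38. That table gives gene spans, so exons and introns were not assigned.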

Results

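The study compared miRNA levels in knee joint cartilage between a control sample and a Col2a1Tsc1KO sample. The control's genotype is labelled wildtype. The knockout's label names the cartilage collagen gene Col2a1 and a knockout of Tsc1, which restrains the growth kinase complex mTORC1. It does not state which cells lack Tsc1. A miRNA array holds no probe for the Tsc1 mRNA, so the labels could not be checked against the targeted gene. There was 1 array per group and thus no replicate check of any difference given here. On the control array 19.6% and on the knockout array 21.1% of the miRNA spots were well above background, and no miRNA spot was saturated. Negative-control spots had a median intensity of 5.02 on the control array and 4.93 on the knockout array, against 98.4 and 107.0 for miRNA spots well above background. At least 1 probe was well above background for 281 miRNAs on the control array and for 296 on the knockout array, and 257 miRNAs were so on both.

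The knockout array carried more signal of miRNAs linked to cartilage and mesenchymal cells and less of the growth-linked miR-17~92 family. At the main setting the mesenchymal miR-214-3p stood highest, at a log2 difference of 2.36 ± 0.03 (SE over spots), or 5.13-fold. It was followed by the p53-induced miR-34a-5p at 2.28 ± 0.04, miR-218-5p at 1.80 ± 0.04 and the cartilage miRNA miR-455-3p at 1.71 ± 0.05. At the other end stood miR-5115 at -1.81 ± 0.09 and the cluster members miR-18a-5p at -1.72 ± 0.03 and miR-17-5p at -1.69 ± 0.06. After normexp these 3 stood at -0.52, -0.93 and -0.64, and miR-214-3p, miR-34a-5p, miR-218-5p and miR-455-3p at 1.504, 1.36, 0.98 and 0.82. In all, 40 of the 257 miRNAs were at least 2-fold higher on the knockout array, 45 were at least 2-fold lower, and 172 lay between. This split depends on the scaling: 59 were higher and 13 lower with no scaling or with the 75th percentile over all probes, 55 higher and 14 lower with the arrays scaled to the added spike-ins, 45 higher and 36 lower with the median, and 40 higher and 35 lower with quantile normalization. With another background correction as well, normexp followed by quantile normalization, 15 were higher and 9 lower. That correction adds an offset of 50 to the intensities, so the log2 differences of dim miRNAs shrink by construction. With total gene signals, counted over a larger set of 304 miRNAs, the split was 80 higher and 24 lower as the software wrote them. With a running sum removed it was 61 higher and 41 lower of the same 304.

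The remaining miRNAs among the 12 highest were miR-196b-5p at 1.69 ± 0.03, miR-193b-3p at 1.69 ± 0.03, let-7e-5p at 1.62 ± 0.02, miR-23b-3p at 1.56 ± 0.01, miR-144-3p at 1.51 ± 0.04, miR-196a-5p at 1.499 ± 0.03, miR-199a-5p at 1.495 ± 0.02 and miR-125a-5p at 1.49 ± 0.04. Both miR-196 members derive from Hox gene clusters. Among the 12 lowest were 4 members of the miR-466 family, miR-466f-3p at -1.67 ± 0.03, miR-466g at -1.56 ± 0.03, miR-466m-3p at -1.54 ± 0.06 and miR-466i-3p at -1.51 ± 0.03, together with miR-669h-3p at -1.68 ± 0.07. The others were miR-3472 at -1.52 ± 0.03, miR-3082-5p at -1.52 ± 0.02, miR-6392-3p at -1.45 ± 0.10 and miR-195a-3p at -1.45 ± 0.06. Under every scaling alternative these 24 miRNAs kept their direction. Across all alternatives the exceptions were 5 of the lowest, which reversed with the software's total gene signals, as did single members of other groups. With every spot required to be well above background, 11 of the 12 highest and 7 of the 12 lowest were still measured. Several were dim on 1 array. On the control array miR-193b-3p and miR-144-3p had scaled intensities of 37.9 and 32.2. On the knockout array miR-466m-3p and miR-195a-3p had 18.7 and 20.1.

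**Figure D1:**
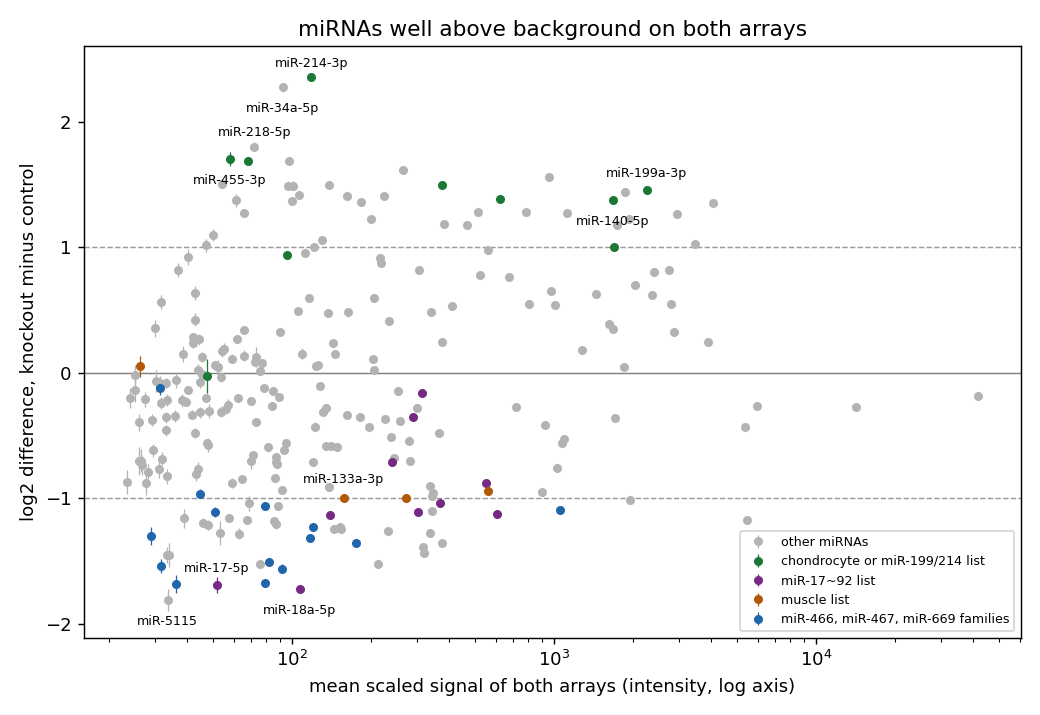
Log2 difference, knockout minus control, against the mean scaled signal of both arrays (log axis) for the 257 miRNAs well above background on both. Bars are standard errors over spots, dashed lines mark 2-fold, and miR-214-3p (2.36) and miR-5115 (-1.81) are the highest and lowest points.

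Of the chondrocyte list, 6 of 9 members were well above background on both arrays and 4 of these were at least 2-fold higher on the knockout array. The list's median log2 difference was 1.19, or 2.28-fold, at percentile 98.4 of random level-matched lists. Both arms of miR-140, which is transcribed under SOX9 control and needed for normal cartilage growth, were bright on both arrays. The scaled intensity of miR-140-5p was 1046 on the control and 2713 on the knockout array, a log2 difference of 1.38 ± 0.01. For miR-140-3p the difference was 1.01 ± 0.01. The longest miR-140-5p probe maps to chromosome 8, positions 107551250 to 107551270, in Mir140 within the span of Wwp2. That of miR-455-3p maps to chromosome 4, positions 63256909 to 63256924, in Mir455 within the span of the collagen gene Col27a1. The other arm, miR-455-5p, differed by -0.03 ± 0.14, less than its standard error. miR-193b-3p (1.69) and miR-365-3p (0.94 ± 0.03) completed the list, while miR-675-5p, miR-675-3p and miR-1247-5p were not well above background on either array.

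All 4 measured members of the list of miR-199 and miR-214 were at least 2-fold higher on the knockout array, with a median of 1.48 at percentile 99.95. Besides miR-214-3p and miR-199a-5p these were miR-199a-3p at 1.46 ± 0.01 and miR-199b-5p at 1.39 ± 0.02. The miR-214-3p probe maps to chromosome 1, positions 162223447 to 162223459, in Mir214 within the spans of Dnm3 and Dnm3os. The list of miRNAs known to target Mtor, Rptor or kinases upstream had a median of 1.32 over 12 members, 8 of them at least 2-fold higher, at percentile 100. Its highest members were miR-218-5p and miR-193b-3p, and its lowest were miR-7a-5p at -0.87 ± 0.04 and miR-101b-3p at 0.03 ± 0.05. The osteoarthritis list, miRNAs followed in studies of diseased cartilage, had a median of 1.12 over 20 members at percentile 99.96, with 12 at least 2-fold higher and 2 at least 2-fold lower. Apart from miR-34a-5p and miR-455-3p at its top, its lowest members were miR-223-3p at -1.17 ± 0.01 and miR-92a-3p at -1.03 ± 0.02. The miR-181 list had a median of 1.06 over 3 members at percentile 97.6, from miR-181d-5p at 0.56 ± 0.05 to miR-181a-5p at 1.23 ± 0.02. These 5 of the 19 lists with a percentile stood in the top 2.5% of random lists. They overlap, since 5 of the 6 measured chondrocyte members and 17 of the 20 osteoarthritis members belong to other lists too. The random lists draw each member separately, although some members share a locus. Probes of miR-199a-5p, miR-199a-3p and miR-214-3p have a listed position within the span of Dnm3os, and those of both miR-140 arms within Mir140. The percentiles can thus rest on fewer loci than members. Over the 13 alternatives their medians ran from 0.72 to 1.62 (chondrocyte), 1.15 to 2.00 (miR-199 and miR-214), 0.72 to 1.79 (mTOR targeting), 0.51 to 1.55 (osteoarthritis) and 0.71 to 1.64 (miR-181). Early-numbered miRNAs in general stood higher: the 98 numbered below 200 had a median of 0.61. Against random lists matched for the range of miRNA numbers as well as for level, a comparison chosen after the data were seen, the percentiles were 97.9 for chondrocyte, 99.7 for miR-199 and miR-214, 99.8 for mTOR targeting, 98.9 for osteoarthritis and 85.4 for miR-181, so the last no longer stood in the top 2.5%, while the miR-17~92 and muscle lists described below were at 0.010 and 0.86.

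All 10 measured members of the miR-17~92 list, which promote cell division, were lower on the knockout array, 6 of them at least 2-fold, though miR-106b-5p and miR-25-3p turn positive with no scaling, the 75th percentile over all probes, spike-in scaling and the software's total gene signals, miR-106b-5p also in the deposited log2 values and with those totals freed of a running sum, and miR-17-5p with the software's total gene signals. Its median was -1.07, or 2.10-fold lower, at percentile 0.845, the 1 list in the lowest 2.5%. Clustered members were again drawn separately, so this percentile too can rest on fewer loci than members. Besides miR-18a-5p and miR-17-5p, miR-92a-3p stood at -1.03, and the smallest differences were those of miR-25-3p at -0.35 ± 0.02 and miR-106b-5p at -0.16 ± 0.01, which are made from another cluster. The miR-17-5p probe maps to chromosome 14, positions 115043694 to 115043706, in Mir17. The list's median stayed negative under all 13 alternatives, from -1.07 to -0.41.

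The other lists with a percentile stood in neither the top nor the bottom range of random lists of their level named above. This does not show that they do not stand apart, because the random lists could draw a list's own members. The random median was 0.54 for the let-7 list and 0.55 for the miR-232724 list, against a median of -0.22 over all 257 miRNAs. All 9 let-7 members were higher on the knockout array, with a median of 0.82 at percentile 86.8, from miR-98-5p at 0.24 ± 0.02 to let-7e-5p. All 5 measured members of the miR-232724 list were at least 2-fold higher, with a median of 1.27 at percentile 96.5, miR-24-3p at 1.44 ± 0.01 and miR-27b-3p at 1.18 ± 0.02. The collagen-targeting miR-29 list had a median of 0.62 over 3 members at percentile 67.0, the miR-30 list 0.49 over 5 members at percentile 86.1, and the miR-15/16 list 0.48 over 6 members at percentile 66.8, from miR-15b-5p at -0.52 ± 0.01 to miR-497-5p at 1.19 ± 0.01. The Runx2-targeting list had a median of 0.36 over 6 members at percentile 90.0. The medians of the miR-29 and Runx2-targeting lists turn negative when dim probes are kept at a floor. That setting adds members not well above background on both arrays, and the miR-29 median was then -0.56, the value of a miRNA at both floors. These turns can thus come from the added members. The inflammation list had a median of 0.13 over 7 members at percentile 77.4 and held miR-146a-5p at 1.49 ± 0.04 and miR-146b-5p at -1.18 ± 0.03. Its median turns negative after normexp, with a floor and in the deposited log2 values. Only 5 of 53 miRNAs of the imprinted Dlk1-Dio3 cluster were well above background on both arrays, with a median of -0.08 at percentile 71.8 whose sign turns under 8 of the 13 alternatives. The hypoxia-induced miR-210-3p, alone of its list, was at 1.42 ± 0.03, and miR-34a-5p was alone of the miR-34 list on both arrays.

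**Figure D2:**
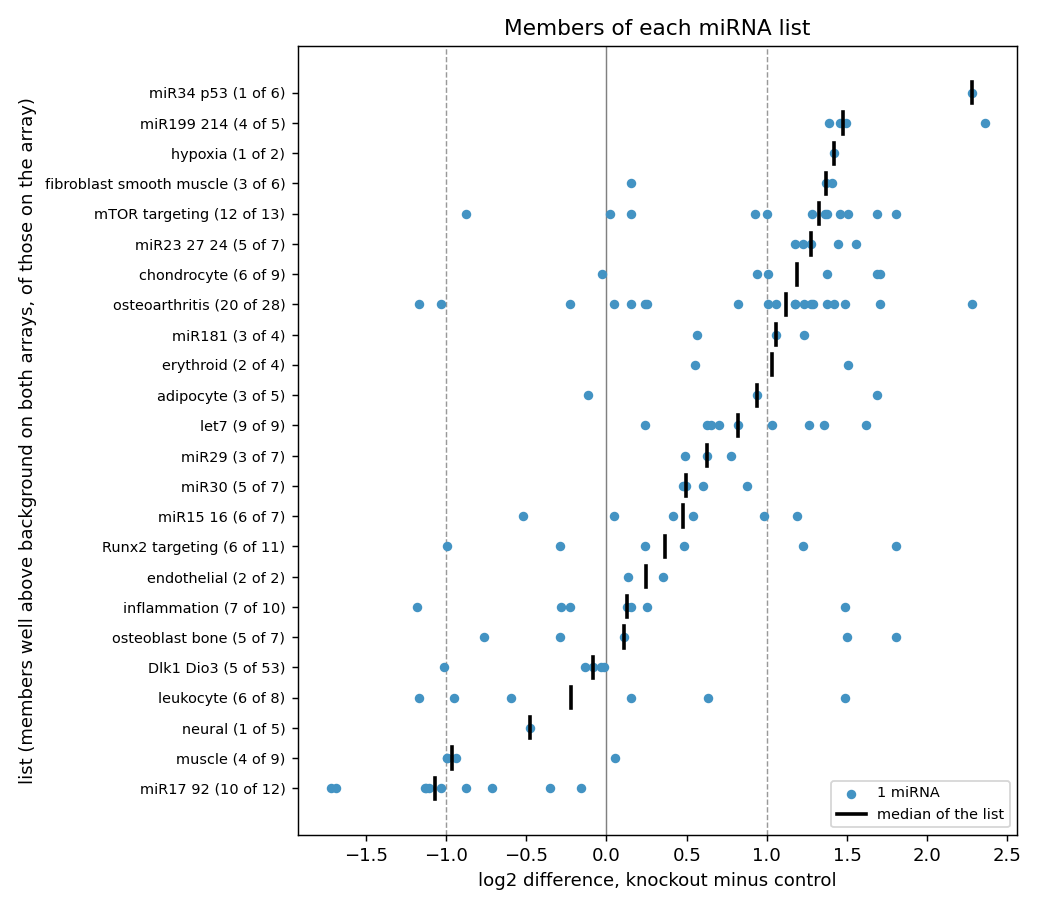
Log2 difference, knockout minus control, of each member well above background on both arrays (points) and the median of each list (bars), with the number of such members and of members on the array in brackets. The miR-199 and miR-214 list (median 1.48) lies near the top and the miR-17~92 list (median -1.07) at the bottom; dashed lines mark 2-fold.

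Markers of other cell types also differed between the arrays, in both directions. The skeletal muscle miRNAs miR-1a-3p, miR-133a-3p and miR-133b-3p stood at -0.94 ± 0.02, -0.99 ± 0.02 and -0.996 ± 0.02, while the dim miR-206-3p was at 0.05 ± 0.08. The muscle list had a median of -0.97 at percentile 5.21, negative under all 13 alternatives. Of the leukocyte list, the myeloid miR-223-3p (-1.17) and the blood cell miRNAs miR-142-3p at -0.95 ± 0.03 and miR-142-5p at -0.59 ± 0.03 were lower on the knockout array, whereas miR-150-5p was at 0.64 ± 0.06, miR-155-5p at 0.15 ± 0.06 and miR-146a-5p at 1.49, of which miR-150-5p turns negative with the software's total gene signals and miR-155-5p with a floor. The list's median of -0.22, at percentile 33.4, turns positive under the 75th percentile over all probes, quantile normalization, no scaling and spike-in scaling. The red cell miRNAs miR-451a and miR-144-3p, the latter also on the mTOR-targeting list, were at 0.55 ± 0.01 and 1.51, and the endothelial miR-126-3p and miR-126-5p at 0.35 ± 0.01 and 0.14 ± 0.04. Of these, miR-451a turns negative with quantile normalization, miR-126-3p with quantile normalization and normexp, and miR-126-5p with a floor. The fibroblast and smooth muscle list had a median of 1.37 (0.39 to 1.80 under the alternatives) over 3 members at percentile 94.8, with miR-10b-5p at 1.41 ± 0.03, miR-143-3p at 1.37 ± 0.02 and miR-10a-5p at 0.15 ± 0.02. The adipocyte list, which shares miR-193b-3p and miR-365-3p with the chondrocyte list, had a median of 0.94 (0.27 to 1.44) over 3 members at percentile 92.5. The osteoblast list had a median of 0.11 over 5 members at percentile 68.1, negative with a floor, from miR-3960 at -0.76 ± 0.01 to miR-218-5p. The neural miR-128-3p was at -0.48 ± 0.04, which turns positive with the software's total gene signals. No epithelial, liver or H19 and Igf2 list member was well above background on both arrays.

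A further 39 miRNAs were well above background on the knockout array alone and 24 on the control array alone. The largest bounds on the knockout side were those of miR-335-5p, at least 2.14-fold higher, and of miR-483-5p, which lies within the span of Igf2, at least 1.93-fold higher. They were followed by the smooth muscle miR-145a-5p at least 1.54-fold, miR-532-5p at least 1.35-fold and miR-362-3p at least 1.34-fold higher. On the control side the largest were miR-883b-5p, at least 2.73-fold lower on the knockout array, miR-467c-5p at least 2.62-fold, miR-669b-5p at least 2.45-fold, miR-468-3p at least 2.39-fold and miR-3098-3p at least 2.33-fold lower. A bound above 1 was reached by 18 of the knockout-side and all 24 of the control-side miRNAs. The bounds were taken at the main scaling alone, and both counts depend on it. With no scaling every knockout-side bound would lie higher, and every control-side bound lower, by 0.41 on the log2 scale. miR-144-5p was well above background on the knockout array alone, and the list members miR-1a-1-5p, miR-1a-2-5p, miR-133a-5p, miR-208b-3p, miR-499-5p, miR-486-3p, miR-223-5p and miR-150-3p were not so on either array.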

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

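Besides the spike-ins, 6 kinds of built-in control probe outside the miRNA comparison gave signal on both arrays far above the negative-control spots, whose median intensity was 5.02 on the control and 4.93 on the knockout array. What these probes detect is not given in the sources used here, and their differences, taken between mean log2 intensities over spots, are unscaled. The bright corner probes had mean log2 intensities of 9.66 on the control and 8.73 on the knockout array, a difference of -0.92. The hur_1 probes stood at 14.32 and 14.00, a difference of -0.32, the hur_6 probes at 14.48 and 14.14, a difference of -0.33, and the mr_1 probes at 11.56 and 11.20, a difference of -0.36, which ran from -0.36 to -0.24 among its single probes. The hur_2 and hur_4 probes differed by 0.022 and 0.081. Comparisons between replicates could not be made with 1 array per group, and no explanation was tested for these values.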

How the results depend on the processing

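Scaling to spike-ins and total gene signals without the running sum were chosen after the data were seen. Relative to the main setting, the median of the 257 miRNAs, -0.22, shifted by 0.43 with the 75th percentile over all probes, 0.41 with no scaling, 0.36 with spike-ins, 0.21 with quantile normalization, 0.21 in the deposited values, 0.18 after normexp, 0.12 with the median, 0.53 with total gene signals and 0.22 with these freed of the running sum. The 4 spike-ins differed between the arrays by a mean of 0.05 with no scaling, while the 75th percentile differed by 0.41. The count at least 2-fold lower, 45, became 13 with no scaling and 13 with the 75th percentile over all probes, and 14 with spike-ins, because these add a constant to every difference. With normexp the counts were 15 higher and 9 lower. This setting adds an offset of 50 to the intensities, which by construction shrinks the log2 differences of dim miRNAs most. How much of the fall in both counts comes from the offset was not tested. Total gene signals gave 80 higher and 24 lower of 304 miRNAs, and 61 higher without the running sum. Thresholds of 1.5-fold and 3-fold gave 84 and 5 lower, and 3-fold gave 7 higher, by their construction. Of the 40 higher miRNAs, 34 stayed at least 2-fold higher with quantile normalization, 34 in the deposited values and 15 after normexp. All other counts of 2-fold differences, and the counts on 1 array alone (34 to 44 for the knockout, 23 for the control), stayed within 1.5 times. Of the named miRNAs at least 2-fold different at the main setting, 5 reversed with the software's total gene signals, miR-17-5p at 5.69, miR-466m-3p at 4.82, miR-466g at 0.55, miR-5115 at 0.41 and miR-195a-3p at 0.33, and none did so under the other alternatives. Of 1068 values of named miRNAs under alternatives, 485 moved by less than the spread over spots, 23 of them to the other sign, and 578 others by more, 57 of them to the other sign, all for miRNAs less than 2-fold different at the main setting. No paired analysis was possible because each group held 1 array. Signal over background limits the dimmest miRNAs: on the control array the lowest probe well above background had an intensity of 21.6, and 927 of 1247 miRNAs were well above background on neither array.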

Other observations

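Among the explanations weighed in this part, the test of probe GC content was set before its result was seen, and the tests of tissue shares, of scaling and of cross-hybridization were chosen after. Tests of 2 further patterns, the spike-ins in the deposited values and the greater signal on the knockout array, were set aside after their results had been seen, and only the values they rested on are given. A first test of less muscle, on how alike 3 muscle miRNAs were, and a comparison of the spread of the miR-466, miR-467 and miR-669 families with random sets were also set aside after their results had been seen, because those members had been picked for their agreement. The patterns were found on these same arrays, and the group and the position on the slide cannot be told apart for any of them.

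For 19 precursors both arms were well above background on both arrays, and the arms of 6 differed in opposite directions, a count that becomes 4 with the arrays scaled to spike-ins. In 2 of the 6, miR-195a and miR-125a, both arms lay at least 0.5 from 0. miR-652 (0.089 for the 5p arm, -0.90 for the 3p arm) and miR-1897 (0.067 and -0.56), chosen after their values were seen, were opposite under all 13 alternatives. miR-455 was opposite under 2 of 12. miR-195a-5p was at 0.98 ± 0.02 and miR-195a-3p at -1.45 ± 0.06. miR-125a-5p was at 1.49 ± 0.04 and miR-125a-3p, chosen after its values were seen, at -0.80 ± 0.06, a mean over 3 probes that ran from -1.86 to -0.18. With the arrays scaled to spike-ins these pairs stood at 1.35 and -1.09, and at 1.86 and -0.44, but with the software's total gene signals miR-195a-3p stood at 0.33, on the side of its partner. A gap of at least 1 between arms was also seen for miR-455 (1.71 for the 3p arm, -0.03 for the 5p arm) and miR-149 (1.099 ± 0.05 for the 5p arm, -0.22 ± 0.05 for the 3p arm), the latter chosen after its values were seen. With spike-ins the arms of each of these 2 lay on 1 side, at 2.07 and 0.34 for miR-455 and at 1.46 and 0.15 for miR-149. With the software's total gene signals both miR-149 arms reversed, to -3.19 for the 5p arm and 1.21 for the 3p arm. Once the running sum described below was removed from these totals, the 5p and 3p arms stood at 1.61 and -0.02 for miR-149. For miR-195a they stood at 1.17 and -1.73. Both pairs were then opposite in the directions of the main setting. By contrast, the arms of miR-199a (1.495 and 1.46), miR-140 (1.38 and 1.01) and miR-126 (0.14 and 0.35) lay within 0.37 of each other.

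The muscle and miR-17~92 lists stood lower and the cartilage and mesenchymal lists higher on the knockout array. A fall by 1 amount in the share of every tissue other than cartilage would lower the markers of all of them alike. Against such an equal fall, the erythroid list median, of 2 miRNAs, lay 2.00 above that of the muscle list on the log2 scale (0.68 to 2.00 under the alternatives). The bright miR-451a alone lay 1.49 above the highest of 3 bright muscle miRNAs, or 0.60 to 1.49 under the alternatives, among which quantile normalization turns miR-451a itself to -0.016. Shares that fall by unequal amounts would also give such gaps, and the scaling sets where 0 lies, so a lower share of every such tissue stays open. Less skeletal muscle in the knockout sample remains open: miR-1a-3p, miR-133a-3p and miR-133b-3p were all lower (miR-1a-3p had scaled intensities of 777 and 406 on the control and knockout arrays) and the muscle list median was -0.97. The dim miR-206-3p was at 0.05, with scaled intensities of 26.0 and 26.9 on the control and knockout arrays, near the lowest signals counted. A 2-fold fall could have removed miR-206-3p from the measured members, so its value decides nothing. The probes of miR-133a-3p and miR-133b-3p are near-identical, so that agreement between them would follow under any cause and decides nothing. Of the leukocyte list, miR-223-3p (-1.17), miR-142-3p (-0.95) and miR-142-5p (-0.59) were lower too, while miR-150-5p, miR-155-5p and miR-146a-5p were higher. A lower share of some tissues but not of every one was not tested and also stays open. A difference that belongs to the genotype stays open as well and was not tested. It cannot be told apart from less muscle or from such a share with 1 array per group.

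Of the miR-466, miR-467 and miR-669 families, a set chosen after its values were seen, 14 miRNAs were well above background on both arrays. All 14 were lower on the knockout array, 12 of them at least 2-fold, with a median of -1.31. miR-669f-3p, the member nearest to 0 at -0.12, turns positive under 8 of the 13 alternatives. miR-466g, miR-466m-3p and miR-669c-3p do so with the software's total gene signals. Scaling is argued against as the whole cause, since the median was -0.94 with the arrays scaled to the spike-ins. Cross-hybridization among near-identical members, which would make the 14 values fewer independent measurements, stays open: the SD of their differences was 0.40, but the set was chosen because its members stood low together, so this decides nothing. A difference that belongs to the genotype also stays open and was not tested.

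The 94 miRNAs numbered 700 and above, which were catalogued later, had a median of -0.50 with 79 of them lower on the knockout array (a median of 0.070 with the software's total gene signals and negative under the other 12 alternatives), whereas the 98 numbered below 200 had a median of 0.61 with 69 higher. The GC content of the probes is argued against as the whole cause: 47 miRNAs numbered below 400 with probe GC content between 51.5% and 71.4%, the middle range of the late-numbered ones, had a median of 0.19 and a lower quartile of -0.19. A part played by GC content stays open. The Spearman correlation of difference and probe GC content was -0.18 over the 257 miRNAs and -0.04 among those numbered below 200. How much of the deficit comes from scaling to the 75th percentile stays open, since the median of -0.13 with the spike-ins reflects a constant added to every miRNA, and it was -0.36 with quantile normalization and -0.40 in the deposited values. The gap between both sets does not depend on a constant factor per array, and its origin, genotype included, was not tested.

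The software's total gene signal held more than a miRNA's own probes for many miRNAs. For 78 of 327 detected miRNAs on the control array and 87 of 348 on the knockout array it equalled, within 0.01, the total of the detected miRNA before it in name order plus the totals of some, not all, of the miRNA's own probes. With any other detected miRNA in place of the one before it, such a match was found for 0.051% and 0.050% on average. On the knockout array miR-17-5p had a total of 2009 although its own probes summed to 16.6, of which 13.3 remain once the total before it is subtracted. The deposited log2 values did not carry this: over the detected miRNAs their Spearman correlation with the totals was 0.603 and 0.592 on the control and knockout arrays, and 1 on both arrays over the 323 and 343 whose totals this rule accounts for, once the running sum was removed. In those values the labelling spike-ins dmr_285 and dmr_31a were lower on the knockout array by log2 differences of -0.89 and -0.63, although the scanner signals differed by 0.02 and 0.17. The same quantile normalization applied to the totals without the running sum gave -0.89 for dmr_285.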
